A study of Mus musculus with 31 samples.

How the data were processed

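The bulk RNA signal values were normalised counts per gene as deposited by the authors, rounded to 1 decimal. Neither the program that counted the reads nor the way the libraries were scaled is given in the sources used here, and whole reads could not be recovered from the values, so the true depth is unknown. The single-cell RNA counts were UMIs per gene and cell in a filtered matrix deposited by the authors, and the single-cell ATAC counts were cut sites per peak and cell together with read pairs per cell. The deposited cell table also gave each cell's TSS enrichment as a ratio and the percent of its fragments in peaks, both computed by the authors before deposit. The submitters' processing notes name mm10, Cell Ranger, Cell Ranger ATAC, Bowtie2, SAMtools and deepTools without versions or settings. Gene names that a spreadsheet had turned into dates were kept as they stood and are not named here.

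The design, the gene lists, the tests and most alternatives were fixed before the data were examined. Groups were taken from the sample labels alone: 31 samples, of which 12 were bulk RNA, 12 bulk ATAC, 6 single-cell RNA and 1 single-cell ATAC. The 12 bulk ATAC libraries were not analysed here. The labels give no expansion of dpi and wpi, which were read as days and weeks after injury, and do not say whether replicates were separate animals, so no replicate block entered the model.

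Bulk values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, using a trended empirical Bayes variance. All 12 libraries entered 1 fit of 6 group means, so that the spread was shared between groups of 2. Of 16301 genes, the 15811 with a value of at least 10 in at least 2 libraries were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. There were 3 contrasts of genotype at each time, their mean, 2 of injury in each genotype and 2 interactions. In total 21 lists of textbook markers and pathways, with 339 genes, were counted over all genes tested and adjusted over the list alone. Each list was also tested with camera at a preset correlation of 0.01 and again with a correlation estimated per list, with 210 tests in all. Of these tests 34 passed with the preset correlation and 0 with the estimated one, where 19 had an unadjusted p under 0.05. A gene listed at 0 in every library of a group has no fold change given.

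Named genes followed a rule. It took Olig2 and Foxj1 always, the 10 highest and 10 lowest log2 fold changes among called genes whose libraries did not overlap and whose mean was at least 50 in 1 group, and up to 4 called members of each list. Examples among these were preferred after their values were seen where the call held in every alternative and without every single library, so they are firmer than the average call. Genes given with values and no test (Olig1, Mbp, Lyz2 and Mki67 between genotypes) were also chosen after their values were seen. Results for some genes are not reported here.

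The single-cell RNA matrix held 3500 cells and 27998 genes, of which the authors' cell table kept 3285 cells and left out 215. Kept cells had between 716 and 52590 UMIs, with a median of 5722. The 6 library codes in the cell names could not be tied to the 6 samples, so the planned comparisons of genotype and time were not made. Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1, 14 clusters). A cluster was named for the marker list with the highest share of members detected in at least 25% of its cells, unless its 10 leading genes or a low UMI count spoke against it. These naming thresholds were set after a first look at the clusters. Levels are UMIs summed over the cells of a class and scaled to a common class total (CPM), with exact Poisson intervals, and shares have exact Clopper-Pearson intervals at the 95% level. Intervals cover counting error only. Lists were set beside 10000 random lists matched on mean expression.

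The single-cell ATAC matrix held 96670 peaks and 1084 cells with the authors' class names. Cells had between 1931 and 181707 cut sites. The gene table, on GRCm38 coordinates, gave no strand, so peaks within 2 kb of either end of a gene stood in for the planned window around its start. Levels are cut sites scaled in the same way (CPM), and shares of cells with at least 1 cut have Clopper-Pearson intervals. Tables were handled with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

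Alternatives for the bulk data were a pseudocount of 8, no filter on low values, median-of-ratios factors, quantile normalization, the replicate number as a block, and each library left out in turn, where the lone library of a group was assumed to vary like the others. Entering the near-identical Foxj1-tdT uninjured libraries as 1 library was chosen after seeing the data, as were comparisons of the single-cell RNA classes within the 2 library codes that held at least 10 progenitor-like cells, and with other reference cells. Without 1 ependymal-like cluster of 383 cells led by immediate early genes, the list of those genes no longer lay outside 95% of matched lists, and results for it in these cells are not reported. The single-cell alternatives changed the cells kept, the Leiden resolution, the doublet filter, the library total, the depth of each cell, the window around genes and the number of cuts asked for. The method was tested on simulated data with 200 changed genes. At 5 dpi it called 10.4% of 2-fold, 43.3% of 4-fold and 63.6% of 8-fold changes, and 2 genes without change. All simulated libraries were drawn independently, with a spread taken from the groups other than Foxj1-tdT uninjured, so they held no near-identical pair. These rates therefore do not measure the error of the main fit, which holds that pair.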

Results

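Ependymal cells line the central canal of the spinal cord and carry motile cilia. The samples came from mice of the C57BL/6 background and 2 genotypes. Foxj1-tdT is named for the ependymal gene Foxj1 and a red fluorescent reporter, and Foxj1-Olig2-tdT adds Olig2, a transcription factor of the oligodendrocyte lineage. The bulk RNA data were 12 Smart-seq2 libraries of ependymal cells obtained by flow cytometry, 2 for each genotype without injury, at 1 dpi and at 5 dpi (read here as days after injury). Their normalised counts summed to between 12601300 and 13878100 per library, and between 14395 and 15379 genes had a value above 0. Single-cell RNA data covered 6 samples pooled in 1 matrix of 3500 cells, and single-cell ATAC data covered 1 sample of 1084 non-neuronal cells of uninjured spinal cord. A further 12 bulk ATAC libraries were not analysed here. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

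Olig2 followed the labels. Its normalised counts were 4.5 and 4.4 in the Foxj1-tdT uninjured libraries, 11.7 and 2.2 at 1 dpi and 17.4 and 195 at 5 dpi. In Foxj1-Olig2-tdT libraries they were 2450.1 and 1690.3 without injury, 3840.5 and 3961 at 1 dpi and 2794 and 3792 at 5 dpi. The 195 in Foxj1-tdT 5 dpi replicate 2 stood apart from the 17.4 of its partner, and Olig1, its neighbour in the oligodendrocyte lineage, read 64.6 and 1159 in the same order. The Foxj1-tdT uninjured libraries were closer to each other than any other pair. Their log2 values correlated across genes at r = 0.989, against 0.864 to 0.928 in the other 5 pairs, and 5 genes were at 0 in 1 library and at 50 or more in the other, against 56 to 412. Because this pair sets part of the spread used in every test, the count of genes with the pair entered as 1 library stands beside each main count. That setting was chosen after seeing the data. Below, a value with ± is a mean with its SD (n = 2), a log2 fold change carries its SE, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

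**Figure D1:**
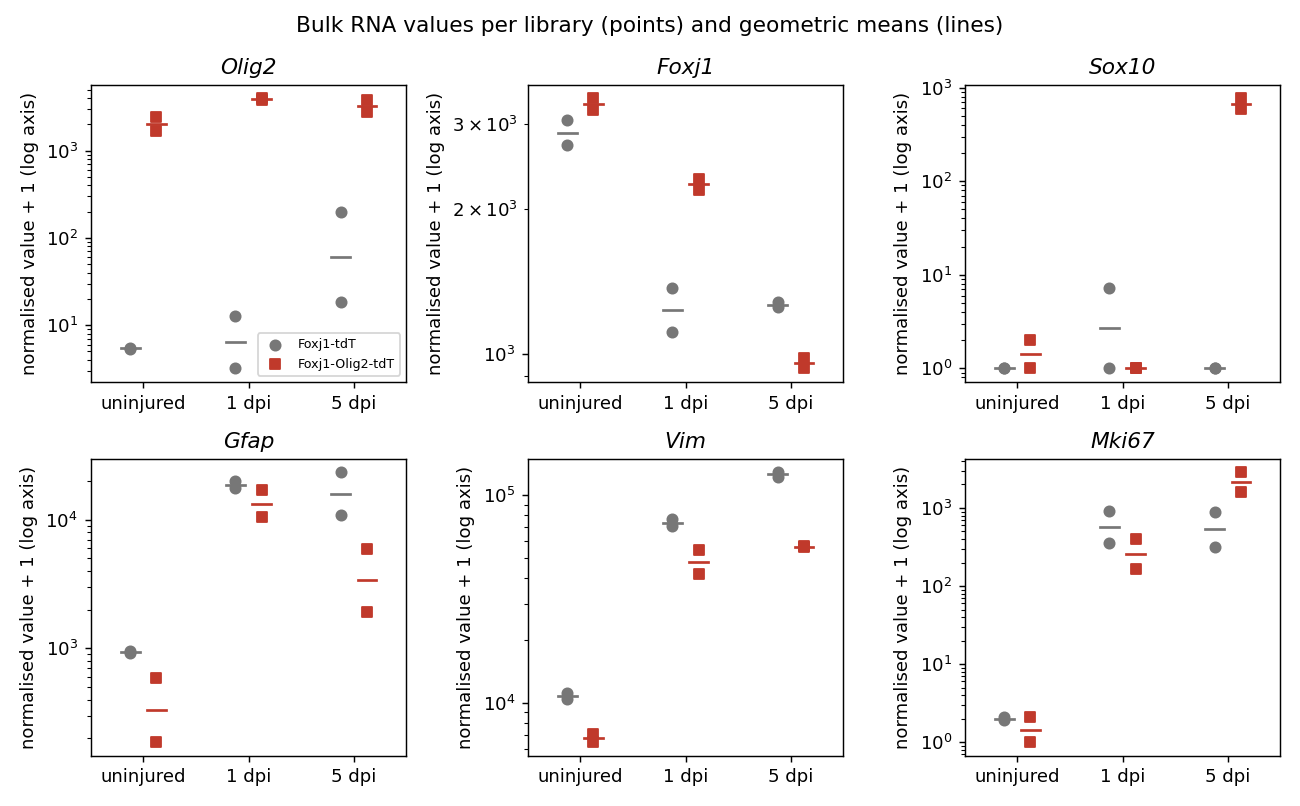
Normalised counts plus 1 on a log axis for 6 genes, with 1 point per bulk RNA library (grey circles Foxj1-tdT, red squares Foxj1-Olig2-tdT) and a line at each geometric mean. Olig2 lay at 1690.3 or above in the Foxj1-Olig2-tdT libraries and at 195 or below in the Foxj1-tdT libraries, and Sox10 rose above 500 in the Foxj1-Olig2-tdT 5 dpi libraries.

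How the genotypes differed 5 days after injury was asked first. Genes of motile cilia were lower in Foxj1-Olig2-tdT cells: of 28 measured members, 25 were lower and 0 higher, with a median log2 fold change of -1.70. The dynein light chain gene Dynlrb2 (log2 fold change -2.23 ± 0.25, adjusted p = 0.000691), the dynein heavy chain gene Dnah11 (log2 fold change -2.25 ± 0.27, adjusted p = 0.00104) and the adenylate kinase gene Ak7 (log2 fold change -2.37 ± 0.32, adjusted p = 0.00199) were among them, while Foxj1 itself read 1266 ± 19.9 in Foxj1-tdT and 958 ± 34.2 in Foxj1-Olig2-tdT cells (-0.40 ± 0.16, adjusted p = 0.158). Mia, which encodes a secreted protein and stood in the same list, showed 9489.9 ± 797 against 73 ± 25.8 (log2 fold change -7.04 ± 0.27, adjusted p = 3.02e-06). Sox10, a transcription factor of oligodendrocyte progenitors and oligodendrocytes, was listed at 0 in both Foxj1-tdT libraries and averaged 678 ± 123 in Foxj1-Olig2-tdT cells (adjusted p = 0.000694). The chemokine gene Ccl2 was likewise listed at 0 in Foxj1-tdT and averaged 477 ± 279.5 in Foxj1-Olig2-tdT cells (adjusted p = 0.000302), and its relative Ccl7 read 2284 and 414 against 1 and 1 (adjusted p = 0.00067).

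Other groups moved in part at 5 dpi. Of 18 oligodendrocyte progenitor genes, 3 were higher and 1 lower, of 16 committed oligodendrocyte genes 1 was higher (Frmd4a, log2 fold change 2.14 ± 0.32, adjusted p = 0.00328), and of 21 myelin genes 2 were higher. The astrocyte list had 1 higher and 6 lower of 15, with the GABA transporter gene Slc6a11 at -4.79 ± 0.70 (adjusted p = 0.00278). Vim, the intermediate filament vimentin, averaged 126191 ± 4379 in Foxj1-tdT and 56425 ± 470.4 in Foxj1-Olig2-tdT cells (log2 fold change -1.16 ± 0.12, adjusted p = 0.000542). The basement membrane collagen Col4a1 was lower too (log2 fold change -3.12 ± 0.44, adjusted p = 0.00228), as was Id4, an inhibitor of helix-loop-helix transcription factors (log2 fold change -2.25 ± 0.31, adjusted p = 0.00199). Gliosis genes went both ways (2 higher, 2 lower of 17), as did neural stem and progenitor genes (2 and 2 of 15), and none of 16 immediate early genes passed. Of 24 cell cycle genes 3 were higher, and the proliferation marker Mki67 read 884 and 319 in Foxj1-tdT against 1612 and 2869.9 in Foxj1-Olig2-tdT libraries. Markers of 5 other cell types (microglia, infiltrating myeloid cells, fibroblasts, pericytes and endothelium) took 0.0626% and 0.0521% of the summed values in the Foxj1-tdT libraries and 0.0868% and 0.0819% in the Foxj1-Olig2-tdT libraries.

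Over all 15811 genes tested, 531 were higher and 929 lower in Foxj1-Olig2-tdT cells at 5 dpi (1460 in all). Adjusted over the list alone, all 28 cilia genes were lower, 16 cell cycle genes were higher, and 6 oligodendrocyte progenitor genes were higher with 1 lower. The set test camera called the cilia list lower (adjusted p = 1.57e-27), the cell cycle list higher (6.67e-08) and the progenitor list higher (0.00722). With an estimated correlation between the genes of a list, the adjusted p = 0.492 for the cilia, 0.492 for the cell cycle and 0.786 for the progenitor list. With the uninjured Foxj1-tdT pair as 1 library 839 genes passed (260 higher, 579 lower), with 22 cilia and 3 astrocyte genes lower, and 1 progenitor gene higher (Sox10) and 1 lower. Without Foxj1-tdT 5 dpi replicate 2 the count was 637, without Foxj1-Olig2-tdT 5 dpi replicate 1 it was 894 and without replicate 2 it was 575, with 114 higher and 461 lower, and without Foxj1-tdT 5 dpi replicate 1 670 were higher and 732 lower. The call of Olig2 itself was lost without Foxj1-Olig2-tdT 5 dpi replicate 2 (log2 fold change 5.54, against 5.76 ± 0.96 and adjusted p = 0.00517 with all libraries), and its log2 fold change was 4.05 without Foxj1-tdT 5 dpi replicate 1 and 7.47 without replicate 2.

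**Figure D2:**
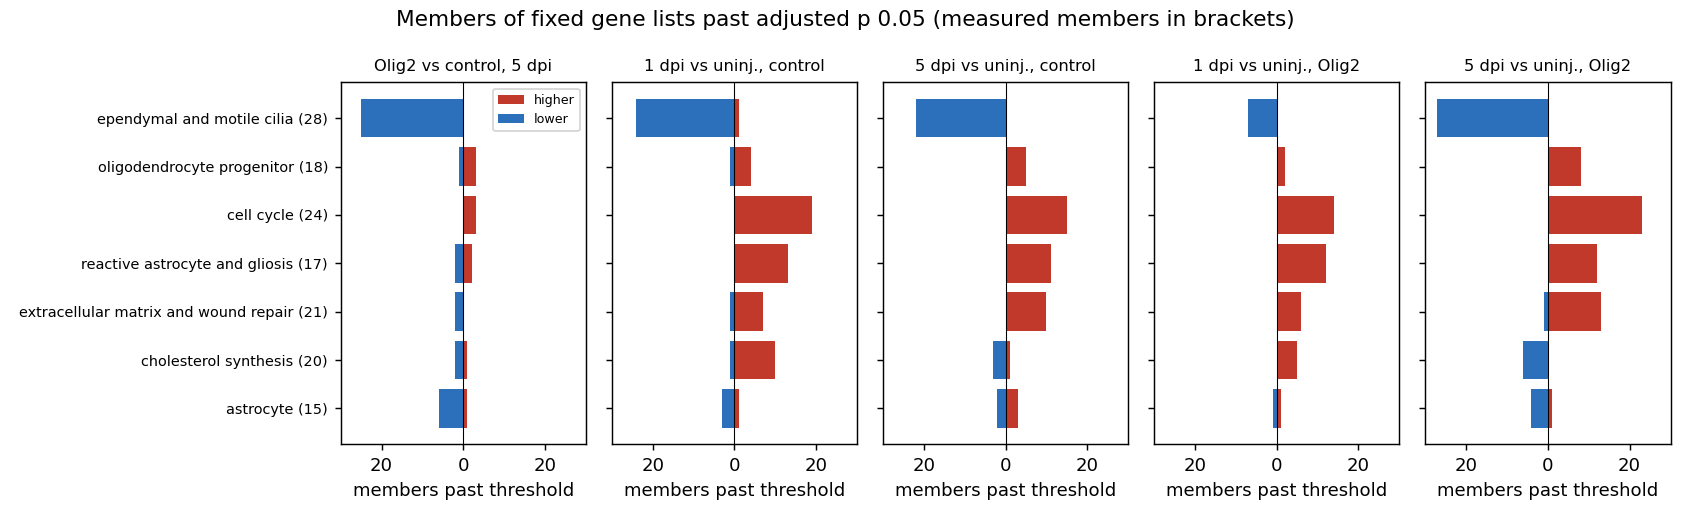
Number of genes past an adjusted p of 0.05 in 7 fixed lists, higher (red, to the right) or lower (blue, to the left), for the genotype comparison at 5 dpi and the 4 injury comparisons. The cilia list had 25 members lower between genotypes at 5 dpi and 24, 22, 7 and 27 lower after injury in the order drawn.

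Before injury, Olig2, Cd44 and Gsn were already higher in Foxj1-Olig2-tdT cells. Olig2 averaged 4.45 ± 0.0707 in Foxj1-tdT and 2070.2 ± 537 in Foxj1-Olig2-tdT cells (log2 fold change 8.55 ± 0.96, adjusted p = 0.00114). The hyaluronan receptor gene Cd44 averaged 3.9 ± 0 against 109.8 ± 25.1 (log2 fold change 4.48 ± 0.42, adjusted p = 0.000526). Gsn, which encodes the actin-severing protein gelsolin, was higher (log2 fold change 6.97 ± 0.56, adjusted p = 0.000261). Of the 28 cilia genes 1 was lower, Mia (log2 fold change -2.70 ± 0.27, adjusted p = 0.000692), and Foxj1 averaged 2882 ± 245 and 3298 ± 126 (adjusted p = 0.517). Of 18 oligodendrocyte progenitor genes 4 were higher, and adjusted over the list alone 4 were higher and 1 lower, and of 24 cell cycle genes 4 were lower, among them Cdk1 (log2 fold change -5.24 ± 0.65, adjusted p = 0.00174). In the cell cycle list 3 genes were higher and 5 lower adjusted over the list alone, and with the pair as 1 library 1 cell cycle gene was lower and 2 progenitor genes were higher. The aquaporin gene Aqp4 read 2521 and 2463 against 8250.4 and 15042, and its adjusted p went from 0.00743 to 0.0829 with the pair as 1 library. Camera called none of the 21 lists in this comparison, with the lowest adjusted p = 0.0977 for immediate early genes. In all 746 genes were higher and 485 lower (1231), and 169 and 66 (235) with the pair as 1 library, 234 of them called in both. The count was 239 without Foxj1-tdT uninjured replicate 1 and 251 without replicate 2, and without Foxj1-Olig2-tdT uninjured replicate 2 the balance turned to 718 higher and 871 lower.

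At 1 dpi, 204 genes were higher and 87 lower in Foxj1-Olig2-tdT cells (291). Olig2 was higher (log2 fold change 9.26 ± 0.96, adjusted p = 0.00264), Aqp4 averaged 951 ± 189 in Foxj1-tdT and 9052 ± 1566 in Foxj1-Olig2-tdT cells (log2 fold change 3.25 ± 0.37, adjusted p = 0.00344), and Gpr37l1, a receptor of glia in the progenitor list, was higher (log2 fold change 2.11 ± 0.19, adjusted p = 0.00264). Ccl7 read 1028 and 1683 in Foxj1-Olig2-tdT against 1.1 and 0 in Foxj1-tdT libraries (adjusted p = 0.00264), and Mia was lower (log2 fold change -2.49 ± 0.27, adjusted p = 0.0029). In the cilia list 8 genes were higher and 2 lower, or 23 and 2 adjusted over the list alone, with a median of 0.88 (camera adjusted p = 3.11e-11, and adjusted p = 0.786 with an estimated correlation). Foxj1 averaged 1241 ± 181 in Foxj1-tdT and 2247 ± 77.1 in Foxj1-Olig2-tdT cells (log2 fold change 0.86 ± 0.16, adjusted p = 0.0307); that call was lost with the pair as 1 library (adjusted p = 0.0802), with the replicate number as a block (log2 fold change 0.86) and without Foxj1-tdT 1 dpi replicate 2 (log2 fold change 0.71), Foxj1-Olig2-tdT 1 dpi replicate 1 (0.90) or replicate 2 (0.83). Camera also called the interferon (0.000242) and cytokine (0.0313) lists higher and the cell cycle list lower (0.00765); of their members 0, 2 and 0 passed, and with an estimated correlation the adjusted p = 0.786 for each. With the pair as 1 library 50 genes were higher and 19 lower (69), and 1 cilia gene was higher and 1 lower. The count was 127 without Foxj1-tdT 1 dpi replicate 2, 163 without Foxj1-Olig2-tdT 1 dpi replicate 1 (83 higher, 80 lower) and 146 without replicate 2, where the balance turned to 65 higher and 81 lower. Of the Foxj1-tdT libraries here, replicate 1 had 0.115% of its summed values in markers of the 5 other cell types and 0.234% in the myelin list, against 0.00788% and 0.0271% in replicate 2.

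Averaged over the 3 times, with 6 libraries against 6, Olig2 was 7.85 ± 0.55 higher on the log2 scale (adjusted p = 0.000242) and Mia was lower (log2 fold change -4.08 ± 0.16, adjusted p = 2.95e-06). Aqp4 (log2 fold change 2.25 ± 0.21, adjusted p = 0.000552) and Ptprz1, a receptor phosphatase of progenitors (log2 fold change 2.01 ± 0.24, adjusted p = 0.00162), were higher. Vim was lower (log2 fold change -0.82 ± 0.07, adjusted p = 0.00042), as was P4ha3, a prolyl hydroxylase of collagen synthesis (log2 fold change -4.92 ± 0.70, adjusted p = 0.00386). Of the oligodendrocyte progenitor list 5 genes were higher and 1 lower (camera adjusted p = 0.00246), and of the cilia list 7 were lower (camera adjusted p = 2.55e-05). With an estimated correlation the adjusted p = 0.786 and 0.999. The mean of the cilia list joins opposite changes, higher at 1 dpi and lower at 5 dpi. Adjusted over the list alone, 8 progenitor genes were higher, and 1 cilia gene was higher and 8 lower. With the pair as 1 library 1 cilia gene was lower and 3 progenitor genes were higher. In all 571 genes were higher and 536 lower (1107), and 179 and 150 (329) with the pair as 1 library. The count was 332 and 345 without Foxj1-tdT uninjured replicate 1 or 2, 684 without Foxj1-tdT 5 dpi replicate 2, and 679 and 576 without Foxj1-Olig2-tdT 5 dpi replicate 1 or 2. Fewer genes were higher than lower without either of the latter (307 against 372, 271 against 305), without Foxj1-Olig2-tdT 1 dpi replicate 1 or 2 (486 against 505, 372 against 430), without Foxj1-Olig2-tdT uninjured replicate 2 (655 against 802) and with a pseudocount of 8 (556 against 588).

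In Foxj1-tdT cells, injury lowered cilia genes and raised genes of gliosis and the cell cycle within 1 day. Of 28 cilia genes 24 fell and 1 rose (median log2 fold change -1.55), with Foxj1 going from 2882 ± 245 to 1241 ± 181 (log2 fold change -1.22 ± 0.16, adjusted p = 0.000551) and Rarres2, which encodes chemerin, falling further (log2 fold change -2.61 ± 0.30, adjusted p = 0.000276). Of 17 reactive gliosis genes 13 rose, among them Cd44, from 3.9 ± 0 to 4911 ± 2457 (log2 fold change 9.87 ± 0.42, adjusted p = 5.23e-06), and the oncostatin M receptor gene Osmr (log2 fold change 8.36 ± 0.64, adjusted p = 4.09e-05). The astrocyte filament gene Gfap went from 939 ± 28.6 to 18722 ± 1578 (log2 fold change 4.31 ± 0.61, adjusted p = 0.000769) and nestin, Nes, a filament of neural progenitors, also rose (log2 fold change 4.88 ± 0.35, adjusted p = 3.25e-05). Of 24 cell cycle genes 19 rose, with Mki67 reading 1.1 and 0.9 without injury and 923 and 349.5 at 1 dpi (log2 fold change 8.15 ± 0.77, adjusted p = 9.68e-05). Of 20 cholesterol synthesis genes 10 rose and 1 fell, with Fdps, farnesyl diphosphate synthase, at 2.58 ± 0.40 (adjusted p = 0.00134). Adjusted over the list alone, 25 cilia genes fell, and 13 gliosis, 21 cell cycle and 11 cholesterol genes rose.

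Camera called the cilia (2.56e-14), gliosis (2.78e-09), cell cycle (2.56e-10) and cholesterol lists (0.00176) at 1 dpi in Foxj1-tdT cells. With an estimated correlation the adjusted p = 0.273, 0.0527, 0.0774 and 0.564 in that order. In all 2427 genes rose and 1904 fell (4331), and 1163 and 592 (1755) with the uninjured pair as 1 library, under which 11 cell cycle and 4 cholesterol genes rose and 0 cholesterol genes fell. The count was 1764 and 1834 without Foxj1-tdT uninjured replicate 1 or 2, and 2837 without Foxj1-tdT 1 dpi replicate 2. Foxj1-tdT 1 dpi replicate 1 had 0.234% of its summed values in the myelin list and 0.115% in markers of the 5 other cell types, against 0.0271% and 0.00788% in replicate 2, and Mbp, myelin basic protein, read 8240 and 162.

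At 5 dpi Foxj1-tdT cells had lower cilia genes than uninjured ones and higher genes of gliosis, the cell cycle and the extracellular matrix. Of 28 cilia genes 22 were lower (median -1.26), among them Ccdc153 (log2 fold change -2.61 ± 0.24, adjusted p = 0.000142) and Tmem212 (log2 fold change -2.34 ± 0.23, adjusted p = 0.000201), and Foxj1 averaged 1266 ± 19.9 (log2 fold change -1.18 ± 0.16, adjusted p = 0.000892). Of 21 matrix and wound repair genes 10 rose, including Tnc, the matrix protein tenascin C (log2 fold change 9.69 ± 1.22, adjusted p = 0.000609), and the type VI collagen gene Col6a2 (log2 fold change 8.20 ± 0.77, adjusted p = 0.000149). Of 17 gliosis genes 11 and of 24 cell cycle genes 15 rose, with Mki67 among them (log2 fold change 8.06 ± 0.77, adjusted p = 0.000162). Id3, an inhibitor of helix-loop-helix transcription factors, was listed at 0 in both uninjured libraries and averaged 1553 ± 937 at 5 dpi (adjusted p = 6.65e-05). Of 18 oligodendrocyte progenitor genes 5 rose. Of 6 measured fibroblast genes 3 rose, with the collagen gene Col1a1 at 842 and 673 against 25.1 and 3.1 (adjusted p = 0.00134), as did 2 of 5 pericyte genes and 1 of 2 infiltrating myeloid genes (2, 0 and 0 with the pair as 1 library). Markers of the 5 other cell types took 0.0626% and 0.0521% of the summed values, against 0.0166% and 0.0164% without injury. Olig2 was called higher (3.46 ± 0.96, adjusted p = 0.027), a call that was lost with the pair as 1 library (adjusted p = 0.135), under quantile normalization (log2 fold change 2.54), without Foxj1-tdT uninjured replicate 1 (3.48) or 2 (3.45), and without Foxj1-tdT 5 dpi replicate 2 (1.76).

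For Foxj1-tdT cells at 5 dpi camera called the cilia (3.39e-14), gliosis (1e-08), cell cycle (8.93e-08) and matrix lists (2.79e-05), and with an estimated correlation the adjusted p = 0.273, 0.0527, 0.133 and 0.249. Adjusted over the list alone, 23 cilia genes fell, and 11 gliosis, 16 cell cycle and 10 matrix genes rose. In all 2186 genes rose and 1456 fell (3642), and 915 and 409 (1324) with the pair as 1 library, under which 15 cilia genes fell and 8 cell cycle and 3 progenitor genes rose. The count was 1317 and 1377 without Foxj1-tdT uninjured replicate 1 or 2.

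In Foxj1-Olig2-tdT cells at 1 dpi, genes of gliosis, the cell cycle and the interferon response were among those that rose. Of 11 cytokine and chemokine genes 2 rose, or 3 adjusted over the list alone, and camera did not call that list (adjusted p = 0.0516, and adjusted p = 0.449 with an estimated correlation). Ccl7 went from 0 and 0 to 1028 and 1683 (adjusted p = 0.000297) and Ccl2 from 1 and 0 to 1462 and 1043 (0.00019). Of 18 interferon response genes 6 rose, or 15 adjusted over the list alone, with Isg15, a ubiquitin-like protein, at 5.38 ± 0.89 (adjusted p = 0.0055) and the transcription factor gene Irf9 at 2.20 ± 0.33 (0.00332). Of 17 gliosis genes 12 rose, or 14 adjusted over the list alone, and Gfap went from 387 ± 284 to 13642 ± 4549.9 (log2 fold change 5.32 ± 0.61, adjusted p = 0.000661). Of 24 cell cycle genes 14 rose, or 17 adjusted over the list alone, among them Mki67 at 396 and 163 against 1.1 and 0 (adjusted p = 0.00044). Cspg4, the proteoglycan NG2 of oligodendrocyte progenitors and pericytes, was listed at 0 without injury and read 146 and 134 at 1 dpi (adjusted p = 0.00347). Of 28 cilia genes 7 fell, or 20 adjusted over the list alone (median -0.74), and Foxj1 averaged 2247 ± 77.1 after 3298 ± 126 without injury (adjusted p = 0.0644). Camera called the cilia (1.22e-12), gliosis (2.67e-14), cell cycle (2.67e-14), interferon (9.49e-09) and cholesterol lists (0.00256, 5 of 20 genes higher), and with an estimated correlation the adjusted p = 0.297, 0.0527, 0.0527, 0.18 and 0.564. In all 937 genes rose and 342 fell (1279), and 602 and 117 (719) with the Foxj1-tdT uninjured pair as 1 library, under which 4 cilia genes fell and 3 interferon genes and 1 cholesterol gene rose. The count was 848 without Foxj1-Olig2-tdT 1 dpi replicate 1 and 742 without replicate 2.

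With all libraries entered, the Foxj1-Olig2-tdT cells at 5 dpi showed the most calls of any comparison. Whether that rank held without 1 of their 5 dpi libraries is unknown. Comparisons that do not use the left-out library were not counted in those fits. Of 28 cilia genes 27 fell (median log2 fold change -3.24): Foxj1 went from 3298 ± 126 to 958 ± 34.2 (log2 fold change -1.78 ± 0.16, adjusted p = 3.04e-05), and Ccdc153 (log2 fold change -4.64 ± 0.24, adjusted p = 1.64e-06) and Rarres2 (log2 fold change -4.62 ± 0.30, adjusted p = 4.89e-06) fell further. Of 24 cell cycle genes 23 rose, with Mki67 at 1612 and 2869.9 against 1.1 and 0 (adjusted p = 9.71e-06) and the kinase gene Cdk1 also higher (adjusted p = 4.57e-06). Of 18 oligodendrocyte progenitor genes 8 rose, among them Sox10, at 0 and 1 without injury and 592 and 765 at 5 dpi (adjusted p = 0.000172), and Cspg4, listed at 0 without injury and at 270 and 64.8 at 5 dpi (adjusted p = 0.000857). Enpp6, a phosphodiesterase gene of newly formed oligodendrocytes, rose too (adjusted p = 0.00223), and 4 of the 16 genes of its list did while 3 fell. Of 21 myelin genes 3 rose and 2 fell, and Mbp read 255 and 114 against 3148 and 991. Olig2 itself was not called between uninjured and 5 dpi libraries of this genotype (0.68 ± 0.96, adjusted p = 0.631).

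Further groups moved in Foxj1-Olig2-tdT cells at 5 dpi. Of 17 gliosis genes 12 rose, and of 21 matrix genes 13 rose and 1 fell, with Tnc (adjusted p = 8.02e-05) and the integrin gene Itga5 (adjusted p = 1.39e-05) among the higher ones. Of 11 cytokine and chemokine genes 3 rose and 2 fell, and 2 of 18 interferon genes rose. Of 15 BMP, Notch and Id genes 4 rose and 1 fell, and so did 4 and 1 of 16 immediate early genes. Of 6 fibroblast genes 4 rose, with Col1a1 at 2468 and 2583 against 2.8 and 6.2 (adjusted p = 6.54e-05), while markers of the 5 other cell types together took 0.0868% and 0.0819% of the summed values against 0.0143% and 0.0102% without injury. Of 15 neural stem and progenitor genes 7 rose, including the cyclin gene Ccnd1 (log2 fold change 5.44 ± 0.48, adjusted p = 2.81e-05), and 3 fell. Of 20 cholesterol synthesis genes 6 fell, among them the regulator genes Srebf2 (log2 fold change -2.09 ± 0.30, adjusted p = 0.000547) and Insig1 (log2 fold change -2.85 ± 0.35, adjusted p = 0.000197). Adjusted over the list alone, 27 cilia and 6 cholesterol genes fell, and 23 cell cycle, 9 progenitor, 12 gliosis and 15 matrix genes rose. Camera called the cilia (4e-25), cell cycle (1.1e-13), gliosis (4.29e-07), matrix (4.61e-05), progenitor (0.0178) and fibroblast lists (0.0178). With an estimated correlation the adjusted p = 0.133, 0.0527, 0.0729, 0.252, 0.456 and 0.297. In all 2716 genes rose and 2210 fell (4926), and 2217 and 1831 (4048) with the Foxj1-tdT uninjured pair as 1 library. The count was 3011 without Foxj1-Olig2-tdT 5 dpi replicate 2. The median gene moved by 0.12 on the log2 scale as deposited and by -0.03 after quantile normalization.

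Whether the injury response differed between the genotypes was tested as an interaction. At 5 dpi, 22 of 28 cilia genes had a more negative log2 change in Foxj1-Olig2-tdT than in Foxj1-tdT cells (median difference -1.86), among them Dnali1 (-2.45 ± 0.29 on the log2 scale, adjusted p = 0.00284) and Mia (-4.35 ± 0.39, adjusted p = 0.00111). The cell cycle genes Mcm5 (4.20 ± 0.61, adjusted p = 0.00525) and Cdk1 (7.36 ± 0.92, adjusted p = 0.00313) and the cyclin gene Ccnd1 (4.50 ± 0.68, adjusted p = 0.00605) had a more positive one. Cdk1 was already lower in Foxj1-Olig2-tdT cells without injury, and that baseline is part of its difference. The collagen gene Col4a1 (-4.58 ± 0.62, adjusted p = 0.00402) and Fdft1, squalene synthase (-2.19 ± 0.31, adjusted p = 0.00476), had a more negative one. Camera called the cilia list lower (4.63e-21), the astrocyte list lower (0.0281) and the cell cycle list higher (2.87e-07, 4 genes passing), and with an estimated correlation the adjusted p = 0.439, 0.714 and 0.439. Adjusted over the list alone, 27 cilia genes were lower and 7 cell cycle genes higher. In all 417 genes were higher and 734 lower in the interaction (1151), and 57 and 167 (224) with the pair as 1 library, under which 9 cilia, 2 cell cycle and 0 astrocyte genes passed. The count was 222 and 215 without Foxj1-tdT uninjured replicate 1 or 2, 641 without Foxj1-tdT 5 dpi replicate 2, 1762 without Foxj1-Olig2-tdT uninjured replicate 2 and 550 without Foxj1-Olig2-tdT 5 dpi replicate 2.

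At 1 dpi the log2 change of Cd44 was smaller in Foxj1-Olig2-tdT than in Foxj1-tdT cells (-4.65 ± 0.59 on the log2 scale, adjusted p = 0.00697) and so was that of Gsn (-6.59 ± 0.80, adjusted p = 0.00614), both of which were already higher in Foxj1-Olig2-tdT cells without injury. Of the cilia list 1 gene was higher, or 8 with 1 lower adjusted over the list alone (camera adjusted p = 1.09e-06, and adjusted p = 0.714 with an estimated correlation). Camera also called the interferon (0.0139) and cytokine (0.0161) lists higher, with 0 and 1 genes passing and the adjusted p = 0.714 for both with an estimated correlation. In all 146 genes were higher and 292 lower (438), and 8 and 34 (42) with the pair as 1 library, under which 0 cilia and 0 cytokine genes passed. The count was 60 and 52 without Foxj1-tdT uninjured replicate 1 or 2, 230 without Foxj1-tdT 1 dpi replicate 2, 747 and 872 without Foxj1-Olig2-tdT uninjured replicate 1 or 2 (464 higher and 408 lower in the latter), 290 without Foxj1-Olig2-tdT 1 dpi replicate 1, and 271 with the replicate number as a block.

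The single-cell RNA matrix gave no comparison between genotypes or times, because its 6 library codes are not tied to samples in the labels, so it was treated as 1 sample. Of 3285 cells the authors kept, 2340 lay in ependymal-like clusters (71.2%, 95% Clopper-Pearson interval 69.7 to 72.8%, counting error only). Mature oligodendrocyte-like cells numbered 126 (3.84%, 3.21 to 4.55%) and oligodendrocyte progenitor-like cells 59 (1.80%, 1.37 to 2.31%), and 760 cells (23.1%) stayed in unnamed clusters. All 5 unnamed clusters matched the ependymal list best, with 21 to 26 of its 28 members detected, but their leading genes or a low UMI count spoke against that name; with them the ependymal-like share would be 94.4%. These shares describe the pool and no single library: all 126 mature-like and 57 of the 59 progenitor-like cells carried the same 2 library codes, which held 42 of the ependymal-like cells. No cluster was named for committed oligodendrocytes (0 of 3285 cells), an outcome of the naming rule that bounds no share of cells. Olig2, which was not among the naming genes, had 509 CPM in progenitor-like cells (443 to 582, Poisson interval), 67.5 in mature-like cells (54.6 to 82.4) and 1.07 in ependymal-like cells (0.61 to 1.73), where the mean of per-cell CPM was 1.87 and the value with each cell thinned to 1000 UMIs 1.72. By their titles the pooled samples include Foxj1-Olig2-tdT, the genotype with high Olig2 values in every bulk library. Whether the UMI counts register the added Olig2 was not tested. The low value therefore does not show that ependymal-like cells of that genotype lacked it. Cholesterol synthesis genes were higher than in ependymal-like cells, with 16 of 19 measured genes higher in each class and a median log2 ratio of 1.44 in mature-like cells, above 100% of 10000 random lists matched on mean expression in both classes. Hmgcs1, HMG-CoA synthase, had 132, 151 and 25.6 CPM in progenitor-like, mature-like and ependymal-like cells. These class comparisons are almost wholly between different libraries. Within the 2 library codes, against the 42 ependymal-like cells there, the median log2 ratio of cholesterol genes was 0.97 in progenitor-like and 0.96 in mature-like cells (percentiles 98.0 and 99.5), and against those together with the 472 unnamed cells of these codes it was 0.80 and 0.99 (percentiles 97.7 and 99.99), comparisons chosen after seeing the data. With Leiden clusters at resolution 0.5 the progenitor-like share was 2.89% (1.61 times), and without the cells of highest doublet score 1.73% of cells were mature oligodendrocyte-like and 2.08% (65 cells) committed oligodendrocyte-like.

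Chromatin at genes of the oligodendrocyte lineage was compared across the authors' 8 cell classes of uninjured cord, EP1, EP2, EP3, ACNT1, ACNT2, OPC, VEC and PER, whose abbreviations the labels do not spell out. At Sox10 (mm10 chromosome 15, 79154913 to 79164490), cut sites within 2 kb of either gene end made up 1.94, 1.90 and 0.55 CPM in EP1, EP2 and EP3 against 72.4 in OPC, and 5.86% of 290 EP2 cells had such a cut (3.45 to 9.22%, Clopper-Pearson) against 64.2% of 67 OPC cells. At Olig2 (chromosome 16, 91225550 to 91228677) the EP classes had 1.94, 5.43 and 6.75 CPM, against 119 in OPC, 243 in ACNT1 and 210.3 in ACNT2. Foxj1 (chromosome 11, 116330704 to 116335499) showed 249.9, 235 and 282 CPM in the EP classes and 89.3 in OPC. The median over the 20 oligodendrocyte progenitor genes was 8.86, 9.98 and 8.94 CPM in EP1, EP2 and EP3 against 44.9 in OPC, and EP cells together held 0.218 of the OPC level. A set of 3980 peaks was chosen for at least 10 CPM in OPC and a CPM there at least 4 times that in VEC and in PER. Of these, 26.1% in EP1, 26.6% in EP2, 23.0% in EP3, 31.4% in ACNT1 and 36.0% in ACNT2 reached at least 0.5 of the OPC level. Choosing peaks on a high OPC value pushes every other class below it, so these shares have no baseline. Median cut sites per cell differed between classes, from 7250 in VEC to 46788 in EP2, so CPM rather than shares of cells set the order.

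**Figure D3:**
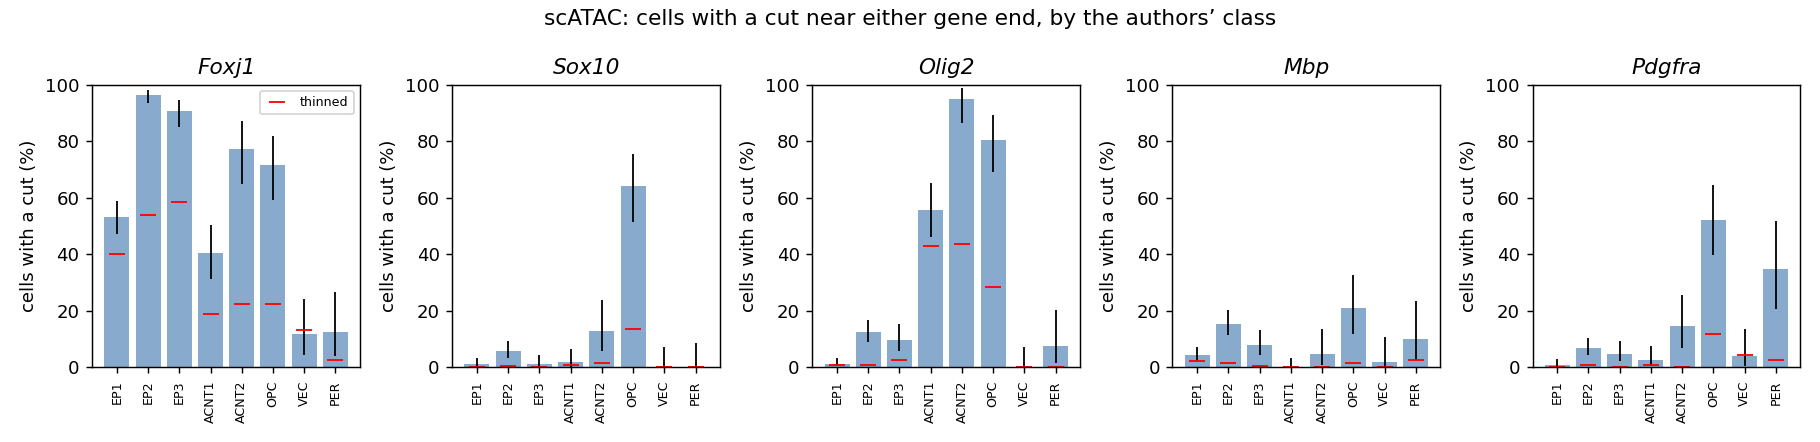
Percent of cells (bars, 95% Clopper-Pearson intervals) with at least 1 cut within 2 kb of either gene end, for 5 genes in the authors' 8 classes, and the same after thinning each cell to 3000 cut sites (red lines). Sox10 was cut in 64.2% of OPC cells and in at most 5.86% of the cells of an EP class.

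The remaining marker lists of other cell types had few measured members in the bulk libraries. Between genotypes at 5 dpi, none of 5 microglia, 2 infiltrating myeloid, 6 fibroblast, 5 pericyte, 6 endothelial and 6 Schwann cell genes passed limma's threshold, over all genes or adjusted over the list alone, while 2 of 10 neuronal genes were higher (0 with the pair as 1 library). After injury to Foxj1-Olig2-tdT cells at 5 dpi, 1 microglia, 1 myeloid, 1 endothelial, 1 Schwann cell and 3 neuronal genes were higher, and 1 pericyte gene was higher and 1 lower. The myeloid gene Lyz2 read 28.8 and 24.1 against 0 in both. The neuronal list gene Stmn2 rose in Foxj1-tdT cells at 1 dpi (log2 fold change 2.47 ± 0.27, adjusted p = 0.000223) and 5 dpi (log2 fold change 1.99 ± 0.27, adjusted p = 0.000928) and in Foxj1-Olig2-tdT cells at 5 dpi (log2 fold change 1.88 ± 0.27, adjusted p = 0.000601). In the single-cell RNA pool Stmn2 had 247 CPM in ependymal-like, 47.1 in progenitor-like and 11.9 in mature-like cells. Its rise therefore need not mark neuronal RNA.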

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

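The tests of how alike the Foxj1-tdT uninjured libraries are, of RNA from other cell types, of how alike the cilia genes fell, and of groupings that keep that pair together were chosen only after the result was seen, as was the use of the planned leave-one-out counts to weigh the pair.

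The injury response differed between the genotypes by the interaction test in 438 genes at 1 dpi and in 1151 genes at 5 dpi, and in 42 and 224 with the near-identical pair as 1 library. At 5 dpi 22 cilia genes had a more negative change in Foxj1-Olig2-tdT cells, and 9 with the pair as 1 library. In the 215 cells that the authors left out of their cell table, microglia markers reached 26205 CPM against 140.2 in the kept cells. Infiltrating myeloid markers reached 29287 against 311 CPM and fibroblast markers 33567 against 146 CPM. Of these cells 176 carried 1 library code and 26 another, so the pooled values set few libraries against all. In the former, microglia markers reached 32321 CPM against 539 in its kept cells and infiltrating myeloid markers 32452 against 2807, and in the latter fibroblast markers reached 166740 against 731. Cilia genes stood at 436 CPM in the left-out cells and at 18428 in the kept cells. The authors' name for their cell table marks it as filtered for MG and Fibro, read here as microglia and fibroblasts. High values of those markers in the left-out cells may therefore follow from how the cells were removed, and are no independent result.

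The Foxj1-tdT uninjured libraries were nearly identical. The median over genes of their squared difference over their sum was 1.32, which was 0.116 of the lowest value in the other 5 pairs, so a candidate explanation is 1 RNA pool sequenced as 2 libraries. Whether it was instead 1 library sequenced again cannot be told apart from the 1.32, since the values are scaled and the true depth is unknown. The labels name no animals, and no biological explanation was tested.

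Calls against that uninjured group may rest on a spread set too small by this pair. In 20 simulations without any change, with the pair drawn from 1 pool, the fit called a median of 3 genes for the uninjured genotype comparison (25 at most) with the pair as 2 libraries and 0 with the pair as 1. At least 20 had been predicted for that explanation and fewer than 5 against it, so the prediction was missed. It was not taken as decisive because the real count was 239 and 251 without Foxj1-tdT uninjured replicate 1 or 2, but 1302 and 1589 without Foxj1-Olig2-tdT uninjured replicate 1 or 2, against 1231 with all libraries, an imbalance that the simulation does not bound. Genes that differ and genes that pass because of the pair cannot be told apart here. Calls with the pair as 1 library rest on 1 Foxj1-tdT uninjured value, the mean of the pair, assumed to vary like the other libraries.

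Cilia genes were lower in Foxj1-Olig2-tdT than in Foxj1-tdT cells at 5 dpi. Markers of microglia, infiltrating myeloid cells, fibroblasts, pericytes and endothelium took at most 0.0868% of the summed values in these libraries, too little for such cells to dilute ependymal RNA by the -1.70 seen in the list. The authors' scaling is argued against by a median of -1.75 under quantile normalization. The myelin list took at most 0.0765% of the summed values and 6 of 15 astrocyte genes were lower and 1 higher, which argues against mature oligodendrocytes and astrocytes as the diluting cells. Oligodendrocyte progenitors stay open: of 18 genes in their list 3 were higher and 1 lower, with a median of 2.10. Dilution by such or other cells without cilia would move the list's members alike. Of 28 members 2 lay more than 3 SE above the list median, with Foxj1 at -0.40 ± 0.16, between the bounds set for and against it. A further 1 lay more than 3 SE below the median, Mia at -7.04, which was already lower without injury. Dilution of the whole list cannot be told apart from a change within ependymal cells by this test. The genotype itself stays open, and may act on cilia genes after injury as a hypothesis found and tested on the same data. The list was not called with an estimated correlation (adjusted p = 0.492).

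Chance as the source of the genotype difference over the 3 times was tested by regrouping libraries within each time. Of 100 such groupings, the real one included, 3 gave as many genes as the real 1107, and the highest other gave 1471. All 3 were among the 34 groupings that keep the near-identical pair in 1 group. With the pair as 1 library 3 of those 34 gave as many genes as the real 329. The highest other gave 387, so chance was not excluded. The possible groupings include some that keep both genotypes whole and only swap their sides at some times. Such groupings still hold a genotype difference and were not set apart, so the counts are not all chance values.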

How the results depend on the processing

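The alternative with the near-identical pair as 1 library, the widening of the ATAC window to both gene ends, the match of random lists on uninjured expression and the comparisons of single-cell RNA classes within 2 library codes or with other reference cells were chosen after seeing the data; all others were planned. Gene counts stayed within 1.5 times the main count for every contrast with a pseudocount of 8, no filter on low values, median-of-ratios factors and quantile normalization. With the replicate block the interaction at 1 dpi went from 438 to 271 genes, and the cause was not tested. With the pair as 1 library the genotype counts were 235 (uninjured), 69 (1 dpi), 839 (5 dpi) and 329 (mean), the injury counts 1755 and 1324 in Foxj1-tdT cells and 719 at 1 dpi in Foxj1-Olig2-tdT cells, and the interactions 42 and 224, in a fit with fewer samples by construction. Of the main calls 234, 69, 839 and 328 were kept for genotype, 1754, 1323 and 716 for injury, and 41 and 223 for the interactions.

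Leaving out each library in turn gave 239 to 1589 genes for genotype without injury, 127 to 268 at 1 dpi, 575 to 1402 at 5 dpi and 332 to 1457 for the mean. For injury it gave 1764 to 3477 and 1317 to 2525 in Foxj1-tdT cells and 742 to 1716 and 3011 to 4899 in Foxj1-Olig2-tdT cells. The interactions gave 52 to 872 genes at 1 dpi and 215 to 1762 at 5 dpi. With 1 library left out, the tests of named genes kept their status (called or not called) 2813 times. In 15 a call was gained and in 968 it was lost, and no called one changed sign. Under the other settings 3800 kept their status, 1 gained a call and 345 lost it. List tests called by camera, over the 21 lists and all contrasts, went from 34 to 0 with a correlation estimated per list, where 19 of 210 tests had an unadjusted p under 0.05. They were 34 with the block and with median-of-ratios factors, 35 with quantile normalization and 35 with the pair as 1 library. Tests on read counts were not run, since whole reads could not be recovered.

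In the single-cell RNA data, Leiden resolution 0.5 gave 63.5% ependymal-like, 2.89% progenitor-like and 29.8% unnamed cells. Without the cells of highest doublet score the shares were 75.6% ependymal-like, 1.73% mature-like, 2.08% committed and 18.8% unnamed, and with at least 1000 UMIs 24.6% were unnamed. The doublet filter took out 7 of the 126 mature-like cells, too few for the fall in their share, so most of that fall came with the new clustering and naming. Causes of the other moves were not tested. As a mean of per-cell CPM, Olig2 stood at 1.87, Foxj1 at 290.7 and Mbp at 52.0 in ependymal-like cells, and Mbp at 11345 in mature-like cells. Without the 20 highest genes in the total, Foxj1 and Mbp stood at 394 and 42.5 CPM in ependymal-like cells, and Sox10 and Mbp at 484 and 10750.2 in mature-like cells. With each cell thinned to 1000 UMIs, Foxj1, Sox10 and Mbp stood at 295 and 1.72 and 44.2 CPM in ependymal-like cells. Thinned progenitor-like cells had 424 for Olig2, 305 for Sox10 and 203 for Mbp, and thinned mature-like cells 47.6 for Olig2 and 11730.2 for Mbp. In the single-cell ATAC data 451 shares of cells stayed within their interval and 317 moved under a wider window, thinning or a limit of 2 cuts. The EP level of the progenitor list relative to OPC went from 0.218 to 0.165 in the wider window and to 0.187 after thinning.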

Other observations

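The match of lists on uninjured expression and the gene groups described first were chosen after values were seen.

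In the uninjured cord the chromatin of other gene groups also differed between the authors' cell classes. Peaks at astrocyte genes had a median of 82.9 CPM in ACNT1 and 83.6 in ACNT2, against 14.9, 23.9 and 19.8 in EP1, EP2 and EP3. Peaks at cilia genes had 46.3, 53.5 and 58.8 CPM in the EP classes and 22.4 in OPC. Peaks at cholesterol synthesis genes had 44.8, 42.8 and 43.0 CPM in the EP classes, 78.6 and 74.0 in the ACNT classes, 68.3 in OPC, 79.9 in VEC and 78.0 in PER.

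The single-cell RNA libraries carry 6 codes that the labels tie to no sample, so their values are given without a group. Ependymal-like cells made up between 4.44% and 93.1% of a library's kept cells, with a median of 86.2%. The 2 libraries with the fewest ependymal-like cells (4.44% and 7.72%) held all mature-like and 57 progenitor-like cells. They also held 472 unnamed cells, all in clusters that matched the ependymal list best, so the naming rule sets these low shares. Oligodendrocyte progenitor-like cells made up between 0 and 9.72% (median 0.106%), mature oligodendrocyte-like cells between 0 and 25.8% (median 0%) and unnamed cells between 6.91% and 76.0% (median 13.7%). Olig2 lay between 0 and 99.6 CPM with a median of 5.68, Sox10 between 0 and 193 (median 2.49) and Foxj1 between 181 and 337 (median 252). Whether these UMI counts register the Olig2 added in Foxj1-Olig2-tdT cells was not tested. Between 337 and 992 cells per library were kept.

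One hypothesis was that genes higher in Foxj1-Olig2-tdT than in Foxj1-tdT cells at 5 dpi could already have more open peaks in the EP classes of uninjured cord. Of 531 such genes 508 had coordinates, and their median EP level was 26.8 CPM, against 28.4 to 34.4 in 95% of lists matched on the mean of the Foxj1-tdT uninjured libraries, at a percentile of 0.17. The values went against the hypothesis. The planned match, on the mean of all 12 libraries (percentile 0), decides nothing, because that mean holds the libraries in which these genes were found higher.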
